A study of Homo sapiens with 12 samples.

How the data were processed

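THP-1, an acute myeloid leukaemia cell line that carries the MLL-AF9 fusion, was treated with 1 of 3 kinase inhibitors or with the vehicle DMSO for 2 hours, and 1 mM 4-thiouridine was present for the last 10 minutes, per the labels' protocols. Each treatment used 1000000 cells. Libraries were made from 3' ends of polyadenylated RNA with a QuantSeq forward kit, and 5% of Drosophila S2 material was added to the purified RNA. AZ5576 is known as an inhibitor of CDK9, THZ531 of CDK12 and CDK13, and YKL5124 of CDK7. The labels give no dose. There were 4 groups of 3 libraries, numbered 1 to 3 in the labels. The labels do not say whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

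The authors deposited whole-number read counts, not normalised, for 295100 rows in 12 libraries. The submitters' processing notes name bcl2fastq 2.17.1.14, Trim Galore 0.6.5, edgeR 3.32.1 and the builds hg38 and dm6. The aligner, the counter, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The 9 inhibitor columns match sample titles by name. The 3 remaining columns carry the name UT, which is not in the labels, so its meaning is not given. They were taken as the DMSO libraries because the labels name this table for all 12 samples. Comparisons between inhibitors do not depend on that step. Only total counts were used, so RNA made during the labelling was not analysed here.

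Rows were named through GENCODE v29 (GRCh38), which held 251529 of 256726 human rows. The 5197 unnamed rows held 0.635% to 0.699% of the counts of a library and were left out of library sizes and tests. The 37 mitochondrial rows held 0 counts, so the list of mitochondrially encoded mRNAs could not be tested. The rows are stretches of transcripts that overlap, and a sum over rows came to 3.30 to 3.39 times the counts of 1 row per gene. The sum per gene had been planned. The row with the highest total over the 12 libraries was used in its place, a change made once the overlap of rows had been seen in the table and before any test was run. A row that gained counts in 1 group alone can be chosen through that group. Both the sum and rows tested on their own were run as alternatives. Of genes with identical counts in every library and a total of at least 120, 1 was kept and 94 were dropped. Processed pseudogenes and their parent genes can share reads, and genes that overlap another gene cannot be told apart from it without the strand setting.

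Depth after this step was 5048370 to 12743630 human counts per library. Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr (minimum count 10), TMM factors were taken over human genes, and 1 quasi-likelihood fit held all 12 libraries with group as the only term. Adjusted p-values are Benjamini-Hochberg values over 15831 genes, with a threshold of 0.05. A standard error is the size of the log2 fold change divided by the root of its F value. CPM are TMM-scaled, and log2 CPM used a prior count of 2. TMM sets changes relative to the middle of the human genes, so a rise is a rise relative to other genes. Of 23 gene lists, 22 were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison. An estimated correlation and fry, which tests whether members move one way on balance and does not compare a list with other genes, were alternatives. The human to fly ratio and the gene length gap per library were compared with exact two-sided permutation tests.

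In data simulated for AZ5576 against DMSO with 15204 genes tested, 67.2% of genes changed 1.5-fold, 73.1% of genes changed 2-fold and 97.0% of genes changed 4-fold were called, and 4.65% of calls were unchanged genes. Only 240 genes were changed in that simulation, whereas 6602 were called for AZ5576 and DMSO in the data. These rates may therefore not hold for the real comparisons. Within groups, pairs of libraries gave a chi-square per gene of 1.73 to 5.00, above sampling noise, so no library was counted as a copy of another.

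The gene lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined. Genes named were 12 preset genes in each inhibitor comparison with DMSO, the 5 largest rises and falls (3 each way between inhibitors) among called genes with a mean of at least 10 CPM in at least 1 of the 2 groups compared, a gene symbol and replicates that did not overlap, and the 2 members of each list with the smallest adjusted p. A gene that this rule names is not reported here. These alternatives were RLE, upper quartile, library size alone and fly scaling, DESeq2 1.42.0, other count filters, only the 6 libraries compared, a replicate block, glmTreat and leaving out each library. Protein-coding genes alone, a run without genes whose last exon overlaps another counted gene, and the use of leave-one-out and summed rows for gene length and overlaps were chosen after seeing the data.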

Results

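Total 3' end read counts of THP-1 cells were compared after 2 hours of AZ5576, THZ531, YKL5124 or DMSO, with 3 libraries per group. Human read counts of replicates 1 to 3 were 12518273, 9798974 and 11820215 in DMSO, 12743630, 5048370 and 12162954 in AZ5576, 8611120, 10326373 and 10761387 in THZ531, and 7776733, 10142436 and 11275189 in YKL5124. AZ5576 replicate 2 was the shallowest library, and it stood apart from AZ5576 replicates 1 and 3 on principal component 3 (29.6 against 4.12 and 2.16). The comparisons ask how RNA levels in these leukaemia cells differ after inhibitors of transcriptional kinases. Coordinates are GRCh38 with GENCODE v29 annotation, and all adjusted p-values of genes come from edgeR's quasi-likelihood test.

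Under AZ5576, transcripts of rapidly induced regulatory genes fell. JUN, a subunit of the transcription factor AP-1, fell by 2.44 on the log2 scale (SE 0.20, adjusted p = 2.26e-11, n = 3 against 3), and its partner FOS fell by 1.54 (SE 0.15, adjusted p = 2.38e-09). HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101), a protein that holds the CDK9 complex inactive, went from 34.3 ± 0.86 CPM in DMSO to 11.6 ± 0.69 CPM (SD, n = 3), a 2.97-fold fall. The anti-apoptotic gene MCL1 fell by 0.90 (SE 0.06, adjusted p = 6.69e-13) and the leukaemia transcription factor MYB fell by 0.68 (SE 0.06, adjusted p = 1.31e-10). In all, 2948 genes were higher and 3654 lower than in DMSO among 15831 tested, of which 378 and 1290 changed at least 2-fold.

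Among the other preset genes under AZ5576, CDK7 fell by 1.07 (SE 0.22, adjusted p = 0.000253), CDK12 by 0.40 (SE 0.07, adjusted p = 5.64e-05) and HOXA9 by 0.22 (SE 0.08, adjusted p = 0.0223). The last exons of HOXA9 and HEXIM1 overlap other counted genes. The call of HOXA9 was lost with upper quartile scaling (-0.17), in DESeq2 (-0.21), without AZ5576 replicate 1 (-0.18) or 3 (-0.18) and without DMSO replicate 1 (-0.17). CDK9 (log2 fold change 0.09, SE 0.17), CDK13 (-0.20, SE 0.11), MYC (-0.28, SE 0.16) and BRCA1 (-0.14, SE 0.07) did not pass the test, although MYC did without AZ5576 replicate 2 (-0.46), and CDK13, MYC and BRCA1 did with fly scaling (-0.38, -0.46 and -0.34). Among genes with a mean of at least 10 CPM in AZ5576 or DMSO, the largest falls were in the pseudokinase gene TRIB1 (ENSG00000173334, chromosome 8, 125430321 to 125438405; log2 fold change -3.13, SE 0.18), OSR2 (-3.08, SE 0.20), C1orf74 (-3.05, SE 0.15), ITPRIP (-2.91, SE 0.16) and WDCP (-2.87, SE 0.21). The largest rises among them were in HMGB1P20 (5.65, SE 0.24), TSPOAP1 (2.46, SE 0.13), ZRSR2P1 (2.23, SE 0.10), H2BC20P (1.94, SE 0.15) and SRP19 (1.87, SE 0.13). HMGB1P20, ZRSR2P1 and H2BC20P are pseudogenes, and ZRSR2P1 and SRP19 overlap REEP5, so the source of their reads is uncertain. HMGB1P20 had 0.444, 0.095 and 0.549 CPM in DMSO replicates 1 to 3, so its fold rests on few counts.

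Of 35 immediate-early genes measured under AZ5576, 28 fell and 0 rose, and 29 fell adjusted over the list alone. Their median log2 fold change was -1.23 (camera adjusted p = 1.15e-21), with IER5 at -2.43 (SE 0.08) and EGR1 at -1.99 (SE 0.07). Of 381 zinc finger genes of the ZNF series, 250 fell and 16 rose, or 257 and 18 adjusted over the list alone (median -0.73, camera adjusted p = 2.18e-18). ZNF503 fell by 2.12 (SE 0.10) and ZNF684 by 1.82 (SE 0.11). Of 21 NF-kB and inflammatory genes, 13 fell and 1 rose, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.000101), among them IRF1 (-2.10, SE 0.13) and the NF-kB inhibitor gene NFKBIA (-0.80, SE 0.07). Of 23 p53 targets, 13 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.88e-06), with GADD45A at -2.07 (SE 0.11) and the pro-apoptotic BBC3 at -1.95 (SE 0.11).

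Nuclear genes of oxidative phosphorylation and of the proteasome were higher relative to other genes under AZ5576 with TMM, but the median of the proteasome was -0.01 with fly scaling. Ribosomal protein genes were called higher with the preset correlation alone (adjusted p = 0.0513 with an estimated correlation). Of 69 nuclear genes of oxidative phosphorylation, 57 rose and 0 fell (59 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 5.48e-10), for example COX8A (0.36, SE 0.06) and ATP5F1C (0.44, SE 0.07). Of 31 proteasome genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 0.00189), for example PSMB2 (0.38, SE 0.07) and PSMB4 (0.32, SE 0.06). Of 79 ribosomal protein genes, 75 rose and 0 fell (76 and 0 adjusted over the list alone), with RPL37 at 0.64 (SE 0.06) and RPL29 at 0.40 (SE 0.06). With fly scaling the list medians came to 0.08 for ribosomal proteins and 0.04 for oxidative phosphorylation, and RPL29 (0.21), COX8A (0.17), ATP5F1C (0.25), PSMB2 (0.19) and PSMB4 (0.12) lost their calls.

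The remaining calls of lists under AZ5576 rested on the preset correlation. The list named monocyte markers also holds granule protein genes such as ELANE and MPO. It had 11 rises and 1 fall of 23, with the same counts adjusted over the list alone (FCER1G 0.43, SE 0.06, and ELANE 0.47, SE 0.07), and an adjusted p = 0.0513 with an estimated correlation. Of 41 G2/M genes 15 fell and 2 rose (17 and 2 adjusted over the list alone), with CCNF at -1.03 (SE 0.07) and AURKA at -0.72 (SE 0.06), and an adjusted p = 0.0513 with an estimated correlation. The BCL2 family had 7 falls and 2 rises of 20 (8 and 2 adjusted over the list alone), and an adjusted p = 0.0580 with an estimated correlation. Among mRNA decay factors 29 of 73 fell and 10 rose (29 and 11 adjusted over the list alone), led by BTG1 (-2.12, SE 0.08) and ZFP36L2 (-1.28, SE 0.08), with an adjusted p = 0.0953 with an estimated correlation. RNA polymerase II kinases and elongation factors had 16 falls and 11 rises of 48 (17 and 11 adjusted over the list alone), including MEPCE (-2.00, SE 0.08) and PPP1R10 (-1.90, SE 0.09), with an adjusted p = 0.151 with an estimated correlation. The stress list had 10 falls and 9 rises of 31 (11 and 9 adjusted over the list alone; DDIT3 -1.97, SE 0.11, and HERPUD1 -1.77, SE 0.11), an adjusted p = 0.265 with an estimated correlation and a median of -0.02 that came to 0.03 with upper quartile scaling. The MLL-AF9 regulators had 13 falls and 3 rises of 26, also adjusted over the list alone (GFI1 -1.18, SE 0.06), and the SR protein and CLK list 12 falls and 3 rises of 29 (12 and 4 adjusted over the list alone; RSRP1 -1.52, SE 0.09, and RSRC2 -1.09, SE 0.09). Both had an adjusted p = 0.327 with an estimated correlation, and the median of the SR protein and CLK list came from -0.05 to 0.00 with upper quartile scaling. Without AZ5576 replicate 3 the camera adjusted p was 0.0599 for the stress list and 0.0544 for both the SR protein and CLK list and the polymerase II list, and without DMSO replicate 3 it was 0.0588 for the stress list. In protein-coding genes alone it was 0.0517 for both G2/M genes and MLL-AF9 regulators, 0.0708 for the SR protein and CLK list, 0.101 for the polymerase II list and 0.122 for the stress list. With upper quartile scaling it was 0.0502 for the SR protein and CLK list, 0.0551 for the polymerase II list and 0.0806 for the stress list, which had 0.0553 with a strict count filter and 0.0763 without one. Without overlapping last exons it was 0.0671 for MLL-AF9 regulators, 0.0991 for the polymerase II list and 0.228 for the stress list.

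No call was made under AZ5576 for 7 lists. G1/S genes had 16 falls and 7 rises of 41, also adjusted over the list alone (CDC25A -1.31, SE 0.07, and CDC6 -0.85, SE 0.08), DNA repair genes 14 and 2 of 46 (12 and 1 adjusted over the list alone; RMI1 -0.87, SE 0.11, and BRCA2 -0.89, SE 0.14), and glycolysis genes 2 and 10 of 19 (2 and 12 adjusted over the list alone; PFKFB3 -0.82, SE 0.09, and ALDOA 0.40, SE 0.06). Small nucleolar RNA host genes had 8 falls and 5 rises of 25, histone genes 4 and 1 of 20, interferon-stimulated genes 4 and 5 of 27, and markers of other cell types 0 and 0 of 4. SNHG12 (-1.47, SE 0.12), SNHG17 (-1.21, SE 0.11), H4C14 (-1.19, SE 0.26), H4C15 (-1.05, SE 0.23), BST2 (0.27, SE 0.06), SAMD9 (-0.48, SE 0.13), PECAM1 (0.13, SE 0.06) and CD79B (-0.72, SE 0.37) had the smallest adjusted p of these lists. Counts adjusted over the list alone were the same for these 4 lists, except 3 falls of histone genes. The interferon-stimulated list had a median of 0.05, a mean of -0.00 and an upward test, with a median of -0.12 with fly scaling, and the other cell types had a median of -0.07, a mean of -0.12 and an upward test. The median of the host genes was -0.01, and 0.05 with upper quartile scaling. The camera adjusted p of glycolysis was 0.0540, and 0.0131 without AZ5576 replicate 2, 0.0397 without DMSO replicate 2 and 0.0453 without YKL5124 replicate 1. With RLE, upper quartile scaling, protein-coding genes alone, summed rows and no low-count filter it was 0.0488, 0.0455, 0.0401, 0.0340 and 0.00927. That of G1/S genes was 0.0636, and 0.0332 without DMSO replicate 2, 0.0174 with library size alone, 0.0255 with fly scaling, 0.0337 with summed rows and 0.00306 without a low-count filter. That of DNA repair genes was 0.199, and 0.00298 without a low-count filter. PECAM1 passed the test without AZ5576 replicate 2 (0.17). It stands in the list of other cell types but had 198, 215 and 203 CPM in DMSO replicates 1 to 3, so these cells express it. With fly scaling FCER1G (0.24), ELANE (0.27), ALDOA (0.20) and BST2 (0.07) lost their calls. The last exons of C1orf74, CCNF, DDIT3, BTG1, ALDOA and SNHG12 overlap other counted genes. TMM centres the genes: with library size alone the median of all genes under AZ5576 was -0.12 and 21.9% of calls were higher, and with fly scaling it was -0.17 and 10.2%, against 44.7% with TMM.

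Under THZ531, HEXIM1, FOS and JUN rose where they had fallen under AZ5576, and MYB fell under both. HEXIM1 rose from 34.3 ± 0.86 to 152 ± 6.8 CPM (SD, n = 3; 4.44-fold, adjusted p = 8.51e-21), FOS rose by a log2 fold change of 1.84 (SE 0.11, adjusted p = 4.28e-15) and JUN by 1.81 (SE 0.12, adjusted p = 6.01e-14). MYB fell by 1.53 (SE 0.06, adjusted p = 6.88e-19), CDK13 by 1.13 (SE 0.12, adjusted p = 2.62e-09) and the repair gene BRCA1 by 0.93 (SE 0.08, adjusted p = 8.58e-12). In all, 4818 genes were higher and 5215 lower than in DMSO, of which 669 and 2775 changed at least 2-fold.

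**Figure D1:**
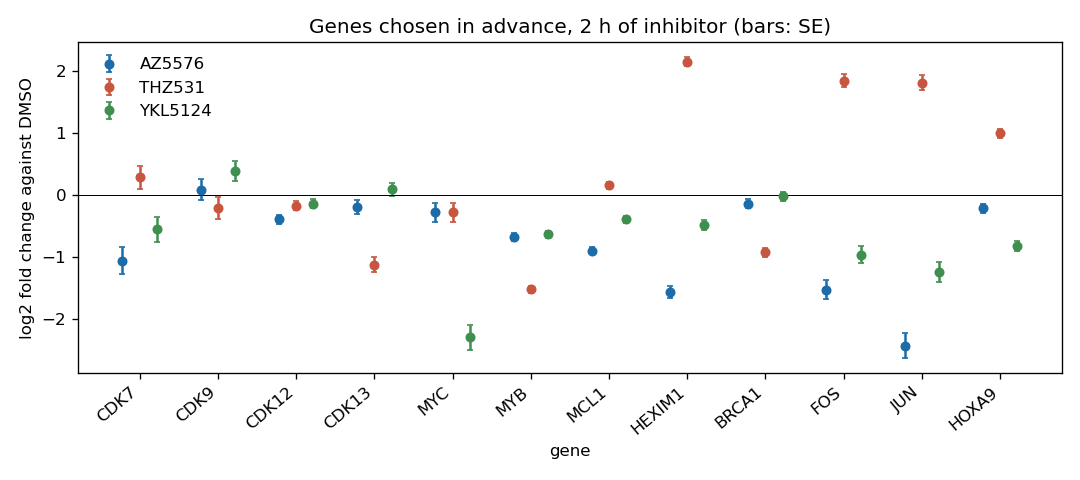
Log2 fold change against DMSO (vertical axis) of the 12 genes chosen in advance (horizontal axis) for each inhibitor, with bars of 1 SE from a fit with 3 libraries per group. JUN, FOS and HEXIM1 lie below 0 under AZ5576 and YKL5124 and above 0 under THZ531, and MYC is lowest under YKL5124 at -2.30.

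HOXA9, a homeobox gene of MLL-rearranged leukaemia, rose by 1.00 (SE 0.07, adjusted p = 6.64e-13) under THZ531. CDK12 fell by 0.17 (SE 0.07, adjusted p = 0.0355), a call lost in DESeq2 (-0.17) and without DMSO replicate 1 (-0.15), DMSO replicate 3 (-0.19) or THZ531 replicate 3 (-0.17). MCL1 was at 0.15 (SE 0.06, adjusted p = 0.0267) with TMM and at -0.14 with library size alone and -0.20 with fly scaling. Its call was lost without DMSO replicate 1 (0.14) or 3 (0.14) and without THZ531 replicate 1 (0.12), 2 (0.13) or 3 (0.13). CDK7 (0.28, SE 0.19), CDK9 (-0.22, SE 0.18) and MYC (-0.29, SE 0.16) did not pass the test, although CDK9 and MYC did with fly scaling (-0.57 and -0.65), and MYC did without AZ5576 replicate 2 (-0.32). Among genes with a mean of at least 10 CPM in THZ531 or DMSO, the largest fall was in PPP1R10 (ENSG00000204569, chromosome 6, 30600400 to 30618612), a regulatory subunit of protein phosphatase PP1, from 93.5 ± 8.0 to 1.29 ± 0.13 CPM (SD, n = 3; log2 fold change -6.16, adjusted p = 1.93e-24). HRH1 (-4.65, SE 0.21), CCDC71 (-4.47, SE 0.19), PDE1B (-4.45, SE 0.22) and PANK1 (-4.11, SE 0.22) followed. The largest rises among genes of that level were in SNORD84 (5.16, SE 0.14), RNVU1-24 (3.96, SE 0.25), RPS20P22 (3.70, SE 0.23), SNORA31B (3.66, SE 0.19) and IER3 (3.50, SE 0.17). SNORD84 and SNORA31B lie within DDX39B and TPT1, RPS20P22 is a pseudogene and IER3 overlaps IER3-AS1, so these reads have an uncertain source.

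Of 35 immediate-early genes, 25 rose and 4 fell under THZ531 (26 and 4 adjusted over the list alone; median 1.07, camera adjusted p = 7.76e-11), with IER2 at 1.70 (SE 0.06) and ID2 at 1.83 (SE 0.07). DNA repair genes had 32 falls and 5 rises of 46, with the same counts adjusted over the list alone (median -0.71, camera adjusted p = 6.10e-05). BARD1, the partner of BRCA1, fell by 1.73 (SE 0.09), while the row used for FANCA, of the Fanconi anaemia complex, rose by a log2 fold change of 3.28 (SE 0.11). That row had 7.25, 6.55 and 5.18 CPM in DMSO and 61.0, 65.2 and 58.4 CPM in THZ531 (replicates 1 to 3). Its counts under THZ531 could have decided its choice, so it may not stand for the whole gene. ZNF genes had 282 falls and 35 rises of 381 (283 and 35 adjusted over the list alone; median -1.13, camera adjusted p = 6.64e-14), led by ZNF557 (-3.55, SE 0.16) and ZNF397 (-2.60, SE 0.12). All 79 ribosomal protein genes rose, also adjusted over the list alone (median 0.51, camera adjusted p = 6.67e-19; RPL24 0.70, SE 0.06, and RPL5 0.63, SE 0.05). Oxidative phosphorylation had 64 rises and 1 fall of 69, also adjusted over the list alone (median 0.44; UQCRB 0.59, SE 0.05, and COX8A 0.55, SE 0.06), and the proteasome 24 and 1 of 31 (25 and 1 adjusted over the list alone; median 0.35; PSMA7 0.64, SE 0.06, and PSMB7 0.59, SE 0.06). With fly scaling these medians were 0.15, 0.08 and 0.00, and UQCRB (0.23), COX8A (0.20) and PSMB7 (0.23) lost their calls.

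The calls of 4 lists under THZ531 were lost with an estimated correlation. The MLL-AF9 regulators had 15 falls and 4 rises of 26, also adjusted over the list alone (RUNX1 -3.52, SE 0.10, and GFI1 -1.80, SE 0.07), with an adjusted p = 0.159 with an estimated correlation. The SR protein and CLK list had 18 rises and 1 fall of 29, also adjusted over the list alone (RSRP1 1.58, SE 0.08, and CLK1 1.58, SE 0.10), and the stress list 21 rises and 6 falls of 31, also adjusted over the list alone (HSPA1B 1.77, SE 0.10, and DDIT3 -2.45, SE 0.12), each with an adjusted p = 0.0961 with an estimated correlation. Glycolysis genes had 13 rises and 2 falls of 19, also adjusted over the list alone (GAPDH 0.70, SE 0.07, and GPI 0.62, SE 0.06), with an adjusted p = 0.132 with an estimated correlation. With fly scaling the medians of glycolysis and of the SR protein and CLK list were -0.02 and -0.03.

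In 12 lists no call was made under THZ531, although members changed. G1/S genes had 21 falls and 13 rises of 41 (POLA2 -1.43, SE 0.09, and MCM10 -1.18, SE 0.08), G2/M genes 18 and 9 of 41 (CCNF -1.85, SE 0.07, and KIF14 -1.14, SE 0.09), and the BCL2 family 8 and 6 of 20 (BCL2 -1.94, SE 0.08, and CFLAR -2.37, SE 0.10). The mRNA decay factors had 26 falls and 22 rises of 73 (SMG9 -2.75, SE 0.13, and RC3H2 -2.25, SE 0.12, but -0.17 with rows summed per gene) and p53 targets 9 and 10 of 23 (ZMAT3 1.73, SE 0.11, and SESN2 1.26, SE 0.09). NF-kB and inflammatory genes had 10 rises and 5 falls of 21 (NFKBIE -1.87, SE 0.12, and REL -0.91, SE 0.07), monocyte markers 14 and 2 of 23 (ELANE 0.58, SE 0.07, and FCER1G 0.47, SE 0.06), host genes of small nucleolar RNAs 12 and 4 of 25 (SNHG9 1.10, SE 0.08, and SNHG25 0.94, SE 0.07), and histones 9 and 2 of 20 (H4C3 0.83, SE 0.08, and H2BC15 2.27, SE 0.32). Polymerase II kinases and elongation factors had 24 rises and 12 falls of 48, with a median of 0.29, a mean of -0.06 and an upward test. Interferon-stimulated genes had 6 rises and 4 falls of 27 (ISG15 0.96, SE 0.11, and XAF1 -0.82, SE 0.10), and markers of other cell types 0 and 1 of 4 (CD79B -1.03, SE 0.40). Adjusted over the list alone the counts of these 12 lists were the same, except 19 falls of G2/M genes, 11 rises of NF-kB and inflammatory genes, 8 rises of histones and 0 falls of other cell types. The call of CD79B was lost without DMSO replicate 2 (-0.85) and THZ531 replicates 1 (-0.94) or 3 (-0.81). The interferon-stimulated list had a median of -0.21 and a mean of -0.07 with an upward test. With fly scaling the medians of monocyte markers, p53 targets, host genes and the polymerase II list went from 0.28 to -0.07, 0.23 to -0.12, 0.06 to -0.29 and 0.29 to -0.07, and FCER1G (0.12), ELANE (0.22) and GPI (0.26) lost their calls. The last exons of CCNF, DDIT3, CFLAR, REL, GPI, H2BC15, SNHG9 and SNHG25 overlap other counted genes. The camera adjusted p of monocyte markers was 0.0519, and 0.0424 to 0.0482 without AZ5576 replicate 1, DMSO replicate 1 or 2, THZ531 replicate 3 or YKL5124 replicate 1 or 3. It was 0.0399 in protein-coding genes alone, 0.0279 with summed rows and 0.00297 without a low-count filter. That of histones was 0.165, and 0.0367 with library size alone, 0.0242 with fly scaling and 0.0398 without a low-count filter. That of p53 targets was 0.165, and 0.0257 without overlapping last exons. That of G1/S genes was 0.223, and 0.0367 with library size alone, and that of the polymerase II list was 0.233, and 0.0408 without a low-count filter. The median of all genes was -0.29 with library size alone and -0.36 with fly scaling, where 23.2% and 13.7% of calls were higher, against 48.0% with TMM.

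Under YKL5124, MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), a transcription factor gene of cell growth, fell from 11.2 ± 1.7 to 2.24 ± 0.24 CPM (SD, n = 3; 4.94-fold, adjusted p = 4.05e-10). JUN fell by 1.25 (SE 0.16, adjusted p = 7.51e-07), FOS by 0.97 (SE 0.14, adjusted p = 4.84e-06), HOXA9 by 0.83 (SE 0.08, adjusted p = 2.68e-09) and MYB by 0.64 (SE 0.06, adjusted p = 1.25e-09). HEXIM1 fell by 0.48 (SE 0.08) and MCL1 by 0.40 (SE 0.06). In all, 1148 genes were higher and 2142 lower than in DMSO, of which 346 and 388 changed at least 2-fold.

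CDK7 itself was at -0.56 (SE 0.20, adjusted p = 0.0463) under YKL5124. That call was lost with RLE (-0.53) and upper quartile scaling (-0.49), in DESeq2 (-0.53), without any of the DMSO replicates (-0.63, -0.52 and -0.54 for 1 to 3), and without THZ531 replicate 1 (-0.55) or YKL5124 replicates 1 (-0.57) or 3 (-0.43). CDK9 (0.38, SE 0.16), CDK12 (-0.14, SE 0.07), CDK13 (0.09, SE 0.10) and BRCA1 (-0.02, SE 0.07) did not pass the test, although CDK9 did with upper quartile scaling (0.45). Among genes with a mean of at least 10 CPM in YKL5124 or DMSO, the largest falls beside MYC were in SNHG12 (-2.81, SE 0.14), whose last exon overlaps TRNAU1AP, in the kinase gene PIM1 (-2.74, SE 0.18), EGR1 (-2.11, SE 0.07) and BHLHE22 (-2.11, SE 0.15), which overlaps BHLHE22-AS1. The largest rises among them were in TSPOAP1 (2.45, SE 0.12), ARTN (2.37, SE 0.19), LINC00562 (1.96, SE 0.16), ZRSR2P1 (1.83, SE 0.10) and ZNF714 (1.79, SE 0.16).

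Host genes of small nucleolar RNAs had 11 falls and 0 rises of 25 under YKL5124 (13 and 0 adjusted over the list alone; median -0.43, camera adjusted p = 1.19e-17). SNHG1 (ENSG00000255717, chromosome 11, 62851988 to 62855914) fell from 118 ± 13 to 30.5 ± 0.64 CPM (SD, n = 3), and SNHG3, which overlaps RCC1, fell by 2.05 (SE 0.09). G1/S genes had 21 falls and 1 rise of 41 (26 and 1 adjusted over the list alone; median -0.30, camera adjusted p = 3.65e-13), among them CDC25A (-1.36, SE 0.07) and E2F2 (-1.59, SE 0.11). G2/M genes had 18 falls and 0 rises of 41 (21 and 0 adjusted over the list alone; CCNF -0.98, SE 0.07, and HJURP -0.75, SE 0.09). Immediate-early genes had 23 falls and 0 rises of 35 (26 and 1 adjusted over the list alone; median -0.66, camera adjusted p = 9.60e-19; IER2 -0.91, SE 0.06). ZNF genes had 126 falls and 12 rises of 381 (140 and 16 adjusted over the list alone; ZNF367 -2.09, SE 0.14, and ZNF503 -1.30, SE 0.09), NF-kB and inflammatory genes 10 and 0 of 21, also adjusted over the list alone (NFKBIA -0.51, SE 0.06, and IRF1 -0.54, SE 0.11), and p53 targets 10 and 0 of 23, also adjusted over the list alone (AEN -1.24, SE 0.08, and BBC3 -1.27, SE 0.10). These 7 lists kept an adjusted p under 0.05 with an estimated correlation.

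A further 9 lists had a call under YKL5124 with the preset correlation alone. The MLL-AF9 regulators had 14 falls and 2 rises of 26 (16 and 3 adjusted over the list alone; GFI1 -1.24, SE 0.06), and the proteasome 3 rises and 0 falls of 31 (1 and 0 adjusted over the list alone; PSMA5 0.39, SE 0.09, and PSMB2 0.20, SE 0.07), both with an adjusted p = 0.0501 with an estimated correlation. The mRNA decay factors had 16 falls and 1 rise of 73 (16 and 2 adjusted over the list alone; ZFP36L2 -1.56, SE 0.08, and BTG3 -1.27, SE 0.10; adjusted p = 0.0541 with an estimated correlation), and DNA repair genes 14 and 1 of 46 (15 and 1 adjusted over the list alone; FANCE -0.68, SE 0.08, and RMI1 -0.88, SE 0.11; adjusted p = 0.0639 with an estimated correlation). Oxidative phosphorylation had 9 rises and 0 falls of 69 (5 and 0 adjusted over the list alone; SDHD 0.79, SE 0.17, and NDUFB1 0.24, SE 0.07), and the stress list 10 falls and 3 rises of 31, also adjusted over the list alone (HERPUD1 -1.61, SE 0.10, and DDIT3 -1.28, SE 0.10), both with an adjusted p = 0.0791 with an estimated correlation. The BCL2 family had 5 falls and 0 rises of 20 (6 and 1 adjusted over the list alone; PMAIP1 -0.78, SE 0.08; adjusted p = 0.0934 with an estimated correlation). Ribosomal protein genes had 10 rises and 1 fall of 79 (4 and 1 adjusted over the list alone; RPL23A 0.25, SE 0.07, and RPL13A -0.25, SE 0.07; adjusted p = 0.237 with an estimated correlation), and the SR protein and CLK list 8 falls and 1 rise of 29 (10 and 1 adjusted over the list alone; RSRC2 -0.86, SE 0.08, and SRSF6 -0.48, SE 0.06; adjusted p = 0.347 with an estimated correlation). No call was made for polymerase II kinases and elongation factors (8 falls and 1 rise of 48; MEPCE -0.93, SE 0.07, and NELFA -0.67, SE 0.08), glycolysis (3 and 2 of 19; SLC2A1 -0.52, SE 0.10, and PFKFB3 -0.46, SE 0.09), interferon-stimulated genes (2 and 2 of 27; IFI35 0.39, SE 0.09, and IFIT3 -0.69, SE 0.20), histones (1 and 1 of 20; H2AC25 -0.76, SE 0.24, and H4C15 0.53, SE 0.19), monocyte markers (0 and 2 of 23; FCER1G 0.30, SE 0.06, and ELANE 0.24, SE 0.07) or markers of other cell types (0 and 0 of 4; CD79B -0.91, SE 0.38, and NKG7 -0.38, SE 0.40). Adjusted over the list alone the counts of these 6 lists were the same, except 7 falls in the polymerase II list and 0 of each in histones.

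Some of these calls under YKL5124 were lost when a single library was left out or with another scaling. The change was no smaller for H4C15 without DMSO replicates 1 or 3 and for PSMB2 without YKL5124 replicates 1 or 2. Those losses came with fewer libraries and not with a smaller change. Without DMSO replicate 2 RPL13A was at -0.14, without DMSO replicate 3 RPL23A was at 0.20, and without YKL5124 replicate 2 RPL23A was at 0.20, each with no call. The call of H2AC25 was lost without DMSO replicate 1 (-0.64) or YKL5124 replicate 2 (-0.59), and that of H4C15 without DMSO replicates 1 (0.54), 2 (0.48) or 3 (0.57) or YKL5124 replicate 2 (0.37). IFIT3 lost its call without DMSO replicate 1 (-0.63) or YKL5124 replicate 3 (-0.60), ELANE without DMSO replicate 2 (0.18) or YKL5124 replicate 3 (0.16), and NDUFB1 without YKL5124 replicates 2 (0.22) or 3 (0.20). PSMB2 lost its call without DMSO replicates 2 (0.16) or 3 (0.17) or any YKL5124 replicate (0.21, 0.21 and 0.16 for 1 to 3). The camera adjusted p of the BCL2 family was 0.0342, and 0.0554 without DMSO replicate 1 and 0.0748 without YKL5124 replicate 2. That of the SR protein and CLK list was 0.0392, and 0.0794 without DMSO replicate 3 and 0.0748 without YKL5124 replicate 3. For the BCL2 family and the SR protein and CLK list these were 0.0919 and 0.127 in protein-coding genes alone, 0.0686 and 0.124 with upper quartile scaling, and 0.0522 and 0.0701 with only the 6 libraries compared. The SR protein and CLK list had 0.0644 with RLE and 0.0561 with a strict count filter. With upper quartile scaling the medians of the stress list, mRNA decay factors and the polymerase II list went from -0.05 to 0.01, -0.04 to 0.02 and -0.02 to 0.05. With fly scaling that of glycolysis went from 0.06 to -0.01, and the proteasome list had a camera adjusted p = 0.112. Calls of FCER1G (0.23), IFI35 (0.32), PSMA5 (0.32), PSMB2 (0.13), NDUFB1 (0.17), ELANE (0.17), H4C15 (0.46), RPL13A (-0.32) and RPL23A (0.18) were also lost with fly scaling, although RPL13A was farther from 0 than with TMM. The interferon-stimulated list had a median of 0.01 and a mean of -0.08 with an upward test. With upper quartile scaling 54.1% and with fly scaling 20.8% of calls were higher, against 34.9% with TMM.

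**Figure D2:**
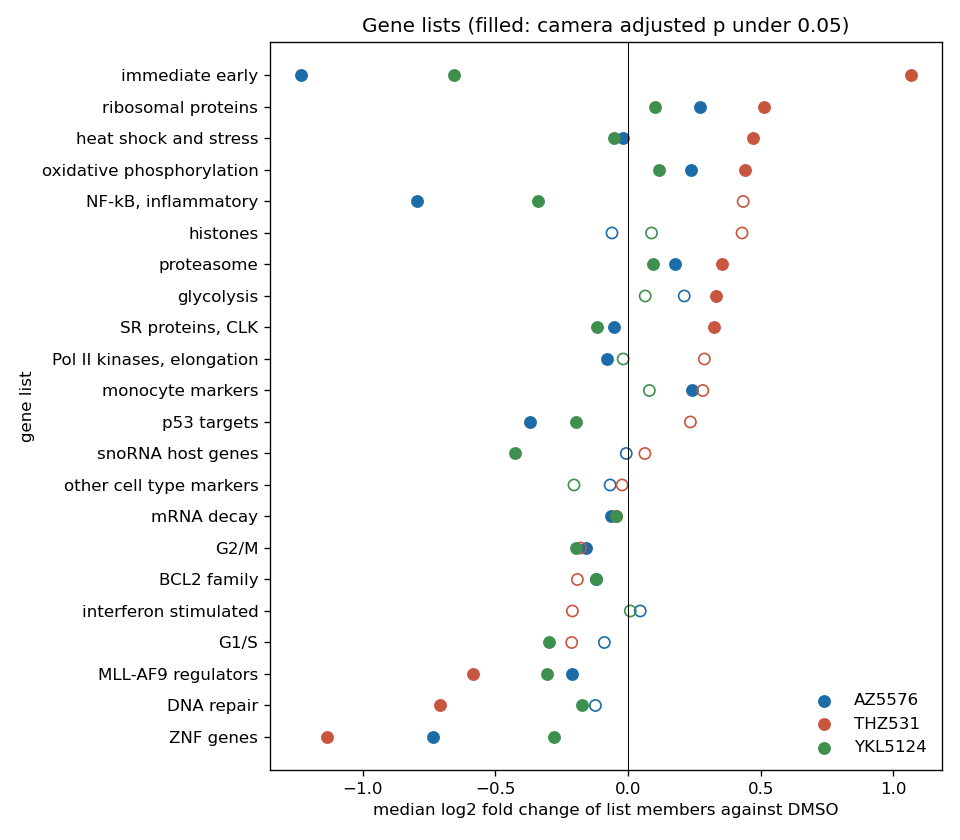
Median log2 fold change against DMSO (horizontal axis) of the members of 22 gene lists (vertical axis), 1 point per inhibitor, filled where the camera adjusted p is under 0.05. The immediate-early list lies at -1.23 for AZ5576, -0.66 for YKL5124 and 1.07 for THZ531.

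Inhibitors were also compared with each other, and the genes named had a mean of at least 10 CPM in 1 of the 2 groups compared. Between AZ5576 and THZ531, 4408 genes were higher and 4300 lower in AZ5576. PLK2 (-6.44, SE 0.40), SERTAD1 (-5.00, SE 0.14) and MICAL3 (-4.92, SE 0.18) were lowest in AZ5576, and HMGB1P20 (5.79, SE 0.26), ATXN7L1 (5.68, SE 0.34) and BCAN-AS1 (4.51, SE 0.29) highest. PLK2 had 0.226 ± 0.32 CPM in AZ5576 and 12.8 ± 0.31 CPM in THZ531 (SD, n = 3), so its fold rests on few counts. With library size alone 67.2% and with fly scaling 69.3% of calls were higher in AZ5576, against 50.6% with TMM.

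Between AZ5576 and YKL5124, 987 genes were higher and 1519 lower in AZ5576. SNHG1 (2.25, SE 0.09), HMGB1P20 (1.79, SE 0.15) and ZNF367 (1.68, SE 0.15) were highest in AZ5576, and SERTAD1 (-2.43, SE 0.17), CDC37L1 (-2.17, SE 0.15) and ITPRIP (-2.14, SE 0.18) lowest. Without YKL5124 replicate 2, 511 genes were higher in AZ5576. With library size alone 10.3% and with fly scaling 7.87% of calls were higher, against 39.4% with TMM.

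Between THZ531 and YKL5124, 4835 genes were higher and 4824 lower in THZ531. IER3 (5.38, SE 0.23), RNVU1-24 (5.37, SE 0.31) and SNORD84 (4.92, SE 0.15) were highest in THZ531, and PPP1R10 (-5.87, SE 0.15), ATXN7L1 (-5.64, SE 0.34) and KRCC1 (-5.56, SE 0.36) lowest. ATXN7L1 (0.193 ± 0.17 CPM) and KRCC1 (0.215 ± 0.28 CPM; SD, n = 3) had few counts in THZ531. In YKL5124 replicates 1 to 3, RNVU1-24 (0.484, 0.186 and 0.249 CPM) and IER3 (0.484, 0.558 and 0.499 CPM) had few counts. With library size alone 25.3% and with fly scaling 21.0% of calls were higher in THZ531, against 50.1% with TMM.

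AZ5576 and YKL5124 shared 843 genes higher and 1840 lower than in DMSO, where independent lists would share 214 and 494, and 23 genes were called in opposite directions (664 for independent lists). AZ5576 and THZ531 shared 1807 and 2126 (897 and 1204 for independent lists), with 1168 in opposite directions (2083), and THZ531 and YKL5124 shared 412 and 1234 (349 and 706), with 852 in opposite directions (1030). All 3 inhibitors shared 350 genes higher and 1095 lower (65 and 163). In 20 simulated sets of unchanged groups against the same DMSO libraries at most 1 gene was shared. Those sets hold no effects and so make few calls, and this does not measure what the DMSO libraries add to the shared genes. Across genes, which are not independent replicates, the covariance of log2 fold changes was 0.309 for AZ5576 and YKL5124, 0.111 for AZ5576 and THZ531 and 0.0153 for THZ531 and YKL5124, against simulated means of 0.0255, 0.0257 and 0.0259. The correlations were 0.778, 0.145 and 0.0275, and the simulated means were 0.456, 0.437 and 0.449. The simulated correlations come from noise alone. They are no baseline for fold changes that hold effects, so a lower value does not mean that 2 inhibitors were less alike than unchanged groups. The DMSO libraries are shared and too few to split, so part of the sharing of genes beyond independent lists may come from them. The covariance was above its simulated mean for the 2 pairs with AZ5576 and below it for THZ531 and YKL5124. Genes higher under all 3 inhibitors came to 197 without DMSO replicate 2, 230 without YKL5124 replicate 2 and 215 without YKL5124 replicate 3, and those higher under THZ531 and YKL5124 to 256, 269 and 273. With fly scaling the genes higher under AZ5576 and THZ531 came to 53, under AZ5576 and YKL5124 to 298, under THZ531 and YKL5124 to 37 and under all 3 to 22. With library size alone AZ5576 and THZ531 shared 432 higher and 3253 lower genes, THZ531 and YKL5124 179 higher, and all 3 inhibitors 123 higher.

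Among 11671 protein-coding genes, the longest quartile (73.9 to 1553.08 kb) had a median log2 fold change of -0.24 under THZ531, and the shortest (0.387 to 13.0 kb) one of 0.10. Under AZ5576 these medians were 0.06 and -0.01, and under YKL5124 0.04 and -0.05. The Spearman correlation of log2 fold change with gene length across genes was -0.150 for THZ531, 0.101 for AZ5576 and 0.154 for YKL5124. It was 0.229 for AZ5576 minus THZ531, -0.212 for THZ531 minus YKL5124 and -0.00534 for AZ5576 minus YKL5124, which came to 0.0232 without AZ5576 replicate 3, 0.105 with the number of exons, -0.120 with the longest transcript and -0.0800 in genes of at least 10 CPM. With the longest transcript in place of the gene the correlation was -0.208 for THZ531, -0.0706 for AZ5576 and 0.00411 for YKL5124. With the number of exons it was -0.0564 for THZ531 and 0.176 for AZ5576, and in genes of at least 10 CPM it was 0.0434 for AZ5576. The number of exons is that of the longest annotated transcript of a gene. Per library, the median log2 CPM of the longest minus the shortest quartile was -0.664 ± 0.0083 in DMSO, -0.883 ± 0.0056 in THZ531, -0.458 ± 0.029 in AZ5576 and -0.475 ± 0.035 in YKL5124 (SD, n = 3). Each inhibitor against DMSO gave an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows.

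**Figure D3:**
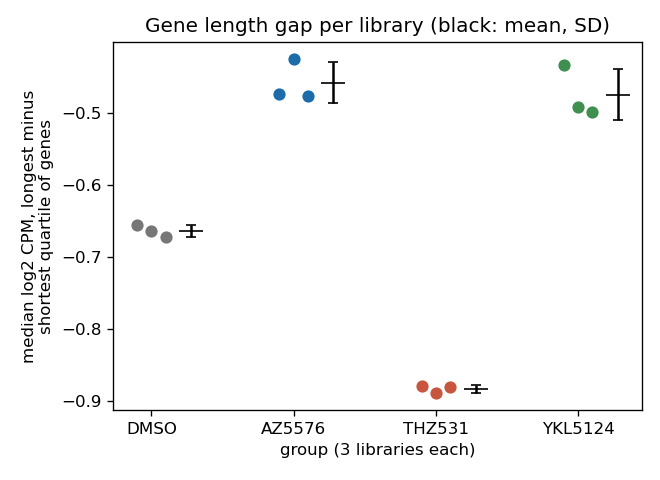
Median log2 CPM of the longest minus the shortest quartile of protein-coding genes (vertical axis) in each library by group (horizontal axis), with the mean and SD of 3 libraries in black. The THZ531 libraries lie near -0.883, below DMSO at -0.664, and those of AZ5576 and YKL5124 lie above DMSO.

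The ratio of human to fly counts was 15.7 ± 2.0 in DMSO, 15.0 ± 1.2 in AZ5576, 15.0 ± 0.66 in THZ531 and 15.2 ± 0.64 in YKL5124 (SD, n = 3). Human counts were those of 1 row per gene, while fly counts were summed over all 11432 distinct fly rows. The level of the ratio depends on that choice and does not give the share of fly material. Only differences between groups can be read from it. Differences from DMSO in the log2 ratio were -0.07, -0.06 and -0.05, with exact two-sided permutation p = 0.7, 0.8 and 0.9, where 0.1 is the smallest possible. Without DMSO replicate 3, the highest library, the differences were 0.03, 0.04 and 0.06. The fly material was added to purified RNA, so this ratio does not measure RNA per cell.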

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

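The tests on scaling, on overlapping genes and on low counts were set before their results were seen, after the patterns themselves had been seen. The test in the quartile of highest expression was chosen after the result was seen. The immediate-early, stress and SR protein and CLK lists and 5 preset genes are given here because 2 inhibitors had called changes in opposite directions, with camera's preset correlation for lists, and the test between them was also passed. Gene length under THZ531 and host genes under YKL5124 do not meet that condition and were chosen after the data were seen.

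Immediate-early genes differed by a median log2 fold change of -2.15 between AZ5576 and THZ531 and of 1.77 between THZ531 and YKL5124, with camera adjusted p = 0.0176 and 0.00161 with an estimated correlation. The smallest median for AZ5576 and THZ531 under 4 other scalings was 0.916 of that with TMM, where under 0.5 would have pointed to scaling. That bound could hardly be reached, because these scalings moved all genes together by little. The median of all genes for AZ5576 minus THZ531 was 0.01 with TMM and at most 0.19, with fly scaling. Shifts of that size do not account for a list median of -2.15. The 32 of 35 members without reads shared with overlapping genes had 0.956 of the full median, so the pattern did not rest on the overlapping members. With so few members dropped, a fall to under 0.5 was hardly possible. A different effect of the kinases inhibited on these genes may account for the pattern, as a hypothesis found and tested on the same data. Doses are not given in the labels, and a difference in the strength of inhibition stays open.

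The gap by gene length under THZ531 is open in part. In the 4 quartiles of mean expression, from lowest to highest, its correlation was -0.0897, -0.0737, -0.140 and -0.195. A value above -0.1 in any quartile had been set in advance as the mark of low counts. That mark was met, by -0.0897 and -0.0737. Yet the correlation was weaker among less expressed genes, and it was -0.173 in genes of at least 10 CPM. These values argue against low counts as the source of the gap among well expressed genes. Without genes that overlap others the correlation was 1.09 times its full size, and with the number of exons in place of length it was -0.0564. With the length of the longest transcript it was -0.208, farther from 0 than the -0.150 with gene length.

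Host genes of small nucleolar RNAs under YKL5124 kept their fall in 2 subsets. Members with a mean of at least 10 CPM had 1.27 times the median fall of all members, and members without overlapping genes had 1.33 times. Both low counts and shared reads are thus argued against, and a biological effect of the inhibitor may account for the fall, as a hypothesis.

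The stress list differed by a median of -0.44 between AZ5576 and THZ531 and of 0.53 between THZ531 and YKL5124. The SR protein and CLK list differed by -0.50 and 0.47, with adjusted p = 0.0600 and 0.0615 with an estimated correlation. Between AZ5576 and THZ531 the log2 fold change was -1.06 for MCL1, -3.72 for HEXIM1, -3.38 for FOS, -4.25 for JUN and -1.22 for HOXA9. Between THZ531 and YKL5124 it was 0.55 for MCL1, 2.63 for HEXIM1, 2.81 for FOS, 3.06 for JUN and 1.83 for HOXA9. The rise of MCL1 under THZ531 was not kept with library size alone or fly scaling.

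With 10 splits of 6 libraries, a share under 0.05 cannot be reached, and in each comparison 1 of the 10 splits, the real one, gave a count as large. In fits on the 6 libraries, the real count and the highest of the other splits were 6152 and 0 for AZ5576 and DMSO, 9727 and 0 for THZ531 and DMSO, and 3185 and 0 for YKL5124 and DMSO. They were 8233 and 0 for AZ5576 and THZ531, 1925 and 1 for AZ5576 and YKL5124, and 9300 and 0 for THZ531 and YKL5124.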

How the results depend on the processing

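Leaving out replicates for the overlaps and for gene length, summed rows for both, protein-coding genes alone and the run without overlapping last exons were chosen after the data were seen. The counts of genes and of lists stayed within 1.5 times their reported size with RLE, without a low-count filter, with a stricter one, in protein-coding genes alone, without overlapping last exons and with rows summed per gene. Counts of genes changed at least 2-fold moved more than that in protein-coding genes alone for 10 of 12 counts and without a filter for 1. Where no cause is named below, the cause was not tested. AZ5576 replicate 2 had the lowest depth, and its depth was not tested apart from other traits of that library. Without it 1409 genes were higher under YKL5124 and 4656 in AZ5576 than in THZ531.

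The replicate numbers did not pair the libraries: the 18 same-numbered pairs had correlations of deviations from -0.102 to 0.0725. With the replicate number as a block, 2919 genes were higher and 3600 lower under AZ5576, 4798 and 5167 under THZ531 and 1107 and 2108 under YKL5124. Lists called were then 14, 11 and 16, with a camera adjusted p = 0.0523 for the stress list under AZ5576 and 0.0418 for monocyte markers under THZ531.

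With fly scaling, higher genes were 504 under AZ5576, 1142 under THZ531 and 518 under YKL5124, 2326 were lower in AZ5576 than in THZ531, and 145 were higher in AZ5576 and 1710 in THZ531 than in YKL5124. Shared higher genes were then 53 for AZ5576 and THZ531, 298 for AZ5576 and YKL5124, 37 for THZ531 and YKL5124 and 22 for all inhibitors. With library size alone, 1328 were higher under AZ5576 and 2198 under THZ531, 273 were higher and 2388 lower in AZ5576 than in YKL5124, and 2369 were higher in THZ531 than in YKL5124. AZ5576 and THZ531 then shared 432 higher and 3253 lower genes, THZ531 and YKL5124 179 higher, and all inhibitors 123 higher. With upper quartile scaling, 2020 were higher under YKL5124. MCL1 under THZ531 turned to -0.20 with fly scaling (edgeR adjusted p = 0.155) and to -0.14 with library size alone (edgeR adjusted p = 0.0560).

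Against a 2-fold threshold with glmTreat, which asks for larger changes, 163 genes were higher and 450 lower under AZ5576, 335 and 1596 under THZ531, and 98 and 46 under YKL5124. Between inhibitors these were 1186 and 812 for AZ5576 and THZ531, 19 and 48 for AZ5576 and YKL5124, and 575 and 1497 for THZ531 and YKL5124. Shared calls of at least 2-fold were 40 higher and 551 lower for AZ5576 and THZ531, 233 and 299 for AZ5576 and YKL5124, 26 and 157 for THZ531 and YKL5124, and 14 and 134 for all inhibitors. With each stretch of the table tested on its own, which tests more features, calls were 5442 and 7457 under AZ5576, 11383 and 11612 under THZ531, and 1744 and 3888 under YKL5124. They were 9684 and 10103 for AZ5576 and THZ531, 2640 lower for AZ5576 and YKL5124, and 11250 and 10546 for THZ531 and YKL5124.

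In DESeq2, 1413 genes were lower under YKL5124 and 609 higher in AZ5576 than in YKL5124. In a fit of the 6 libraries compared, 641 were higher in AZ5576 than in YKL5124. With an estimated correlation 6 lists were called under AZ5576, 6 under THZ531 and 7 under YKL5124, and fry called 20 under THZ531.

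The length correlation of AZ5576 turned to -0.0706 with transcript length, and was 0.176 with the number of exons and 0.0434 in genes of at least 10 CPM. That of THZ531 was -0.208, -0.0564 and -0.173, and -0.118 with summed rows. That of YKL5124 was 0.00411 with transcript length. AZ5576 minus THZ531 gave 0.181 with transcript length, 0.173 with exons and 0.194 with summed rows. AZ5576 minus YKL5124 gave -0.120 with transcript length, -0.0800 in genes of at least 10 CPM, and turned to 0.105 with exons. THZ531 minus YKL5124 gave -0.125 with exons, -0.227 in genes of at least 10 CPM and -0.182 with summed rows.

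Leaving out each library in turn gave 511 to 1183 genes higher in AZ5576 than in YKL5124, with the lowest value without YKL5124 replicate 2. It gave 256 to 537 shared higher genes for THZ531 and YKL5124 and 197 to 459 for all inhibitors, with the lowest values without DMSO replicate 2. The length correlation ranged from -0.153 to -0.147 for THZ531 and from -0.221 to -0.203 for THZ531 minus YKL5124. Of 207 values of named genes, 24 lost their call and kept their sign with fly scaling, 3 with library size alone, 7 in DESeq2 and 8 with summed rows, and MCL1 under THZ531, above, lost its call and turned under both scalings. Among the tests of lists, 7 lost their call in protein-coding genes alone, 5 with upper quartile scaling, 3 without overlapping last exons, 2 with only the 6 libraries compared, 2 with a strict count filter, 1 with RLE, 1 without a low-count filter and 1 with fly scaling. Calls were gained by 6 without a low-count filter, 3 with library size alone, 3 with summed rows, 2 with fly scaling, 2 in protein-coding genes alone, 1 with RLE, 1 with upper quartile scaling and 1 without overlapping last exons. The alternative on newly made RNA was not run, since only total counts were used.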

Other observations

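The tests on exon number, low counts and upstream ends were set before their results were seen, after single-exon genes had been noticed among the falls under AZ5576. Kinds of genes were compared after the data were seen, with no test of one kind against another.

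Small nucleolar and Cajal body RNAs were the kind of gene with the highest share of rises under THZ531: 55 of 96 rose and 9 fell, with a median log2 fold change of 0.67, and 39 rose at least 2-fold. Under AZ5576 19 rose and 15 fell, and under YKL5124 13 rose and 17 fell. Long non-coding genes had 693 falls and 290 rises of 1586 under THZ531 (median -0.53), and 165 falls and 265 rises under YKL5124 (median 0.06). Pseudogenes had 741 rises and 250 falls of 2242 under THZ531, with a median of 0.24. Pseudogene rows held 12.1% to 14.1% of the human counts of a library. Whether these were reads of parent genes was not tested, so the rises may not be of the pseudogenes themselves. Small nucleolar RNAs lie in introns of other genes as a rule, and whether reads of the host genes were counted for them was not tested. With library size alone the median of all genes under THZ531 was -0.29.

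That protein-coding genes with 1 exon fell more than other genes under AZ5576 is a hypothesis, noticed and tested in the same libraries. The exon number is that of the longest annotated transcript of a gene, so other transcripts of these genes can have more exons. Of 410 such genes, 188 fell and 58 rose, with a median log2 fold change of -0.32, against -0.01 for 11261 genes with more exons. In 10000 lists matched on mean expression and gene length the median had a 95% range of -0.05 to 0.05, and the difference from their middle was -0.315. Among genes with a mean of at least 10 CPM the difference was -0.213, so low counts are argued against. RNA decay was not measured by these counts. Under THZ531 the medians were -0.05 and -0.05, and under YKL5124 -0.18 and -0.02.

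Loss of full-length transcripts under THZ531 could show as a gain of upstream 3' ends, and this was not found at the size set in advance. Over 5725 genes with 2 counted ends at least 500 bases apart, the median change in log2 upstream over downstream counts was 0.0792 under THZ531, below the bound of 0.1, although the 3 THZ531 libraries (0.0740 to 0.0914) lay above the DMSO libraries (-0.0161 to 0.00705). Among pairs with at least 100 counts at both ends the change was 0.365 of that, under the 0.5 set in advance as the mark of low counts. Low counts may thus account for part of the change, which was itself below its bound. Rows of 1 gene can hold the same reads, which would shrink such a change.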
